A study of Mus musculus with 8 samples.

How the data were processed

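RNA of mouse embryonic fibroblasts of 4 genotypes, 8 samples with 2 for each genotype, was measured on 1-colour Illumina mouse BeadArrays. Per the labels' protocols, total RNA was column-purified with DNase digestion and labelled as biotinylated cRNA with a kit for Illumina arrays. The deposited non-normalized table holds each probe's average intensity on a linear scale and a detection p-value, the share of negative controls at least as bright, per the file headers. Per the submitters' processing notes, GenomeStudio 2011.1 was used; what it was used for is not given in the sources used here. A second table of the authors holds processed intensity values of the same arrays. Set against the raw table it kept each array's rank order (Spearman's rho 1), had column medians from 8.856 to 8.884 and had 34.5% of values below 0. It therefore looks linear, background-subtracted and scaled between arrays, but its exact method stays unknown. No slide or scan batch is recorded in the tables used here, and the layout of samples over BeadChips was not analysed.

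Intensities were corrected and normalized with limma 3.58.1 in R 4.3.3 (neqc: normexp using negative controls inferred from the detection p-values, offset 16, quantile normalization, log2). Probes with a detection p under 0.01 in both arrays of at least 1 genotype were kept, 14867 of 45281 (32.8%). Of all probes 34885 had 1 gene symbol in the platform annotation, 18 several and 10378 none, and genes are named only from probes with 1 symbol. Of the named probes 34807 matched the mouse gene table (assembly GRCm38.p6) by gene identifier, which was used for names and for which genes neighbour each other. A linear model with 1 mean per genotype was fitted to all 8 arrays with lmFit and eBayes (residual df 4, prior df 3.79), and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Where a probe was not well above background on any array of a genotype, the difference is given as a bound: the brighter genotype's mean against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes above background. A fold change of a dim probe is otherwise understated by the offset.

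For gene lists, the kept probe with the highest mean stood for each gene, and 28 lists were tested with camera (preset correlation 0.01), adjusted over lists within each contrast. The model, the contrasts, the lists, the alternatives and the rule for named genes were set before the data were examined. That rule takes Gadd45a and Ing1, the 10 largest rises and falls against WT and the 5 largest in other contrasts among called probes whose groups did not overlap, and up to 4 of the most changed called members of each list. Numbered replicates share only a number in the labels and were not treated as pairs. Alternatives covered background correction, normalization, the authors' processed values, filters, a replicate block, eBayes and array weights, thresholds, set tests and each array left out. Leaving out an array lowers the residual df of the whole fit. A call can then be lost with little change in size, even where that array lies outside the contrast.

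The fit was tested on simulated data drawn for the real probes with their fitted variances. For DKO minus WT, over 14867 probes with 200 changed and 20 draws, it recovered 10.8% of probes changed by 0.5 log2 units, 85.9% of those changed by 1 and 98.5% of those changed by 1.5, with 5.42% of calls false. In the list test for the same comparison (8655 genes), a list of 30 genes moved by 0.3 was called in 20 of 20 draws and none of 540 unmoved lists was called. That simulation has independent probes, so it does not speak to lists whose genes vary together. Both simulations also gave each probe the same variance in every genotype, as the fit assumes. In the real data the median SD between replicates was 0.122 in WT and 0.0893 in DKO. The simulated share of false calls therefore need not hold for the real calls.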

Results

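Gene expression was measured in mouse embryonic fibroblasts, primary cells grown out of embryos, that carried both, one or neither of the genes Gadd45a and Ing1. Gadd45a encodes a small protein induced by stress and DNA damage, and Ing1 encodes a chromatin-binding member of the inhibitor of growth family. Per the labels, the cells came from male C57BL/6 embryos and were collected confluent at passage 3. The 8 arrays fall into 4 genotypes of 2: wild type (WT), Gadd45a-/-, Ing1-/- and the double knockout (DKO). The design text describes duplicates per fibroblast line, so both arrays of a genotype may come from 1 line. Genotype and line then cannot be told apart, and all p-values measure only the spread between these arrays, which may be technical. Between 14277 and 14778 of the 45281 probes were above background on an array, and 14867 probes covering 8655 named genes were tested. Replicate arrays correlated across probes with Pearson's r from 0.9876 (WT) to 0.9937 (DKO), and probes are not independent replicates. Arrays of different genotypes reached 0.9898, and a WT array reached 0.9889 with another genotype, above the value between the 2 WT arrays on which every comparison with WT rests. The number of arrays limits the precision of every value.

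The targeted genes were examined first. Both Gadd45a probes were above background on all 8 arrays and were brighter, not dimmer, on the arrays labelled Gadd45a-/- and DKO. The first probe read 10.82 ± 0.16 in WT, 11.82 ± 0.02 in Gadd45a-/-, 10.13 ± 0.02 in Ing1-/- and 11.74 ± 0.08 in DKO (log2 normalized intensity, mean ± SD, n = 2 arrays). Against WT it was higher by 1.00 ± 0.12 in Gadd45a-/- (log2 fold change ± SE, limma adjusted p = 0.011) and by 0.92 ± 0.12 in DKO (limma adjusted p = 0.0071). The second probe was higher by 1.29 ± 0.15 in Gadd45a-/- (limma adjusted p = 0.0091) and by 1.31 ± 0.15 in DKO (limma adjusted p = 0.0038). In Ing1-/- neither difference from WT passed the threshold, with log2 fold changes of -0.69 (limma adjusted p = 0.074) and -0.45 (limma adjusted p = 0.31). The first Gadd45a probe's call in Gadd45a-/- was lost without WT replicate 2 (limma adjusted p = 0.0539) or Gadd45a-/- replicate 1 or 2 (0.0847 and 0.0832), and in DKO without DKO replicate 1 or 2 (0.0761 and 0.05). The second Gadd45a probe's call in Gadd45a-/- was lost without Gadd45a-/- replicate 1 or 2 (0.057 and 0.0765) and in DKO was kept. The Gadd45a signal therefore goes against the label, unless the probes lie outside the deleted part, whose position is not given in the sources used here; a probe outside it checks nothing. Every direction below is drawn for arrays as labelled Gadd45a-/-, Ing1-/- or DKO. The single Ing1 probe was not well above background on any array, WT included, and so checks no label. For each of the Y-linked genes Eif2s3y, Kdm5d and Uty, 1 probe was above background on all arrays and the others on none. No Xist probe was above background on any array. The labels give the cells as male.

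**Figure D1:**
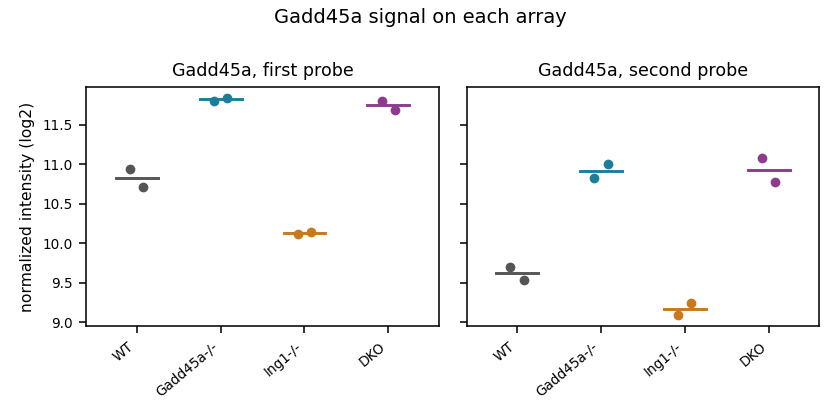
Normalized log2 intensity of both Gadd45a probes on each array (points, 2 per genotype) with the genotype mean (line); the vertical axis is in log2 units. The arrays labelled Gadd45a-/- and DKO sit above the WT arrays at both probes, by 1.00 and 0.92 at the first and by 1.29 and 1.31 at the second.

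The comparison of arrays labelled Gadd45a-/- with WT asks what changed with the loss of Gadd45a alone, as far as the label holds. Col2a1, the main collagen of cartilage, was 14.1-fold higher (log2 fold change 3.81 ± 0.13, limma adjusted p = 3.5e-05), and its other 2 probes passed as well. Bmp4, a bone morphogenetic growth factor, was 4.05-fold higher, and Acan, the cartilage proteoglycan, was at least 1.24-fold higher, since it was not well above background in WT. List counts take 1 probe for each gene, the brightest. Of 7 measured cartilage and bone markers 3 rose and none fell (median log2 change 1.28, camera adjusted p = 5.66e-05, adjusted p = 0.109 with an estimated correlation). Adjusted over the list alone, 5 were higher and 1 lower. The list was not called with no detection filter (camera adjusted p = 0.33). A further matrix-associated gene, Smoc1, was 5.77-fold higher.

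Markers of macrophages and blood also rose in Gadd45a-/-, 6 of 10 measured, and none fell (median log2 change 0.90, camera adjusted p = 4.23e-13, adjusted p = 0.0946 with an estimated correlation). All 10 were higher when adjusted over the list alone. C1qb, a subunit of complement C1q, was 3.66-fold higher (log2 fold change 1.87 ± 0.17, limma adjusted p = 0.0034), with 1 of the 2 WT arrays above background. C1qc was higher by 1.36 ± 0.23, again with 1 WT array above background, the Fc receptor chain Fcer1g by 1.02 ± 0.15, and Cd52 at least 2.06-fold. Epithelial markers moved the same way, 2 of 6 measured rising (median 0.77, camera adjusted p = 0.00497, adjusted p = 0.144 with an estimated correlation). These were Sfn, at least 1.87-fold higher, and Pkp1, a desmosomal plaque protein, higher by 1.19 ± 0.15 with 1 of the 2 WT arrays above background. The epithelial call was lost without WT replicate 1 (camera adjusted p = 0.0697).

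Genes of the integrated stress response, the programme downstream of ATF4, were lower in Gadd45a-/- (28 measured, median -0.33, camera adjusted p = 7.71e-11, adjusted p = 0.109 with an estimated correlation). Trib3 fell by 1.01 ± 0.17 and Chac1 fell by 0.61 ± 0.11, the other 26 did not pass over all probes, and 10 were lower when adjusted over the list alone. A second probe of Asns passed too, falling by 0.83. Interferon response genes passed as a list (21 measured, median -0.36, camera adjusted p = 3.47e-07, adjusted p = 0.109 with an estimated correlation). None passed singly over all probes and 6 were lower over the list alone. Extracellular matrix genes were lower on balance (40 measured, 4 falling and 1 rising, median -0.20, camera adjusted p = 2.61e-05, adjusted p = 0.21 with an estimated correlation). The collagen-binding proteoglycans Lum and Dcn fell by 1.44 ± 0.19 and 0.89 ± 0.12, Lum with 1 of the 2 Gadd45a-/- arrays above background, Col3a1 fell by 1.15 ± 0.20, and elastin (Eln) rose by 1.57 ± 0.23. Of 25 measured senescence and secretory genes 3 fell, namely the collagenase Mmp13 by 1.31 ± 0.12, the gelatinase Mmp9 by 1.20 ± 0.14 and the chemokine Cxcl1 by 0.78 ± 0.14 (median -0.11, camera adjusted p = 0.00201, adjusted p = 0.109 with an estimated correlation). Cholesterol synthesis genes were lower as a list with no single call among 16 (median -0.25, camera adjusted p = 0.000574, adjusted p = 0.21 with an estimated correlation). Contractile genes (28 measured, median 0.11, Myh11 the single call, adjusted p = 0.21 with an estimated correlation) and cell cycle genes (38 measured, median 0.08, no call, adjusted p = 0.361 with an estimated correlation) passed as higher, both at a camera adjusted p of 0.0459. The contractile call was lost without WT replicate 1 (camera adjusted p = 0.165), Gadd45a-/- replicate 2 (0.229) or DKO replicate 1 or 2 (0.0582 and 0.0571), with the authors' processed values (0.0579) and with all probes of each gene (0.133). The cell cycle call was lost without WT replicate 2 (camera adjusted p = 0.274), Gadd45a-/- replicate 2 (0.507), Ing1-/- replicate 1 (0.0688) or DKO replicate 1 or 2 (0.0582 and 0.0571).

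Among other named genes, Il1rn, the interleukin 1 receptor antagonist, was at least 2.64-fold higher, the carbonyl reductase Cbr2 at least 1.99-fold, and the homeobox gene Lhx9 at least 1.96-fold. Mid1 was at least 2.42-fold higher. Erdr1 was at least 3.73-fold higher at 1 probe, the other not being above background in either genotype, and Pde4dip rose by 1.92 at 1 probe while its other 3 were not called. The largest falls were those of Nt5c3, a pyrimidine nucleotidase (by 1.57 ± 0.13), the homeobox gene Msx1 (by 1.49 ± 0.25, with 1 Gadd45a-/- array above background), the mitochondrial protein Chchd10 (by 1.39 ± 0.15), Itgbl1 (by 1.32 ± 0.22), Moxd1 (by 1.28 ± 0.22) and the transcription factor Osr2 (by 1.21 ± 0.20). Nt5c3 lies within 25 Mb of Gadd45a, and a strain variant near that gene is taken up below. In total 138 probes rose and 60 fell (limma, adjusted p under 0.05). The total of 198 became 77 or 69 without WT replicate 1 or 2, 37 or 40 without Gadd45a-/- replicate 1 or 2, 100 without either DKO array and 129 without Ing1-/- replicate 2. Bmp4, C1qb, Cbr2, Col2a1, Erdr1, Il1rn, Lhx9, Mid1, Mmp13, Nt5c3, Pde4dip and Smoc1 stayed past the threshold whichever array was left out. The other genes named for this comparison did not, save the second Asns probe, for which this was not examined.

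The comparison of Ing1-/- with WT asks what changed with the loss of Ing1 alone. Macrophage and blood markers were higher here too (10 measured, median 0.66, camera adjusted p = 2.54e-09, adjusted p = 0.157 with an estimated correlation). Over all probes C1qb alone passed, higher by 1.60 ± 0.17 (limma adjusted p = 0.014) with 1 of the 2 WT arrays above background, and over the list alone 7 were higher. Fcrls, an Fc receptor-like gene, was at least 2.31-fold higher. Bmp4 rose by 1.58 ± 0.15 and Col2a1 by 1.29 ± 0.13. The Col2a1 call was lost without WT replicate 1 or 2 (limma adjusted p = 0.0545 and 0.0559) or Ing1-/- replicate 1 or 2 (0.0838 and 0.117), and its other 2 probes, dim in WT, were not called. The cartilage list as a whole did not pass (median -0.05, camera adjusted p = 0.214), its median and the direction of its test differing in sign. Emcn, an endothelial sialomucin, was at least 2.21-fold higher.

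Interferon response genes were lower as a list in Ing1-/- (21 measured, median -0.38, camera adjusted p = 2.54e-09, adjusted p = 0.157 with an estimated correlation), as were those of the integrated stress response (28 measured, median -0.32, camera adjusted p = 2.54e-09, adjusted p = 0.157 with an estimated correlation). No member of either passed over all probes, while 7 and 12 were lower over the list alone. The oxidative stress list was lower with no member past the threshold over all probes (21 measured, median -0.18, camera adjusted p = 0.000169, adjusted p = 0.157 with an estimated correlation). Of 25 senescence and secretory genes 3 fell: Igfbp3, an insulin-like growth factor binding protein, by 1.62 ± 0.22 with 1 of the 2 Ing1-/- arrays above background, Mmp13 by 1.15 ± 0.12 and Cxcl1 by 0.94 ± 0.14 (median -0.03, camera adjusted p = 0.022, adjusted p = 0.157 with an estimated correlation). That list's call was lost without WT replicate 2 (camera adjusted p = 0.0729) and without Ing1-/- replicate 1 (camera adjusted p = 0.0575), with no detection filter (0.0669) and with all probes of each gene (0.0841). Lum was at least 2.68-fold lower, the only call among 40 matrix genes at the brightest probe of each (list median -0.10, camera adjusted p = 0.015, adjusted p = 0.368 with an estimated correlation), and the list's call was lost without WT replicate 1 (camera adjusted p = 0.0731) and without Ing1-/- replicate 2 (camera adjusted p = 0.141) and with median scaling (0.0565). A second probe of Dcn was also called, at -1.04. Contractile genes (28 measured, median 0.16, camera adjusted p = 0.0105, adjusted p = 0.157 with an estimated correlation) and pericyte markers (7 measured, median 0.33, camera adjusted p = 0.022, adjusted p = 0.254 with an estimated correlation) passed as higher with no member called. Both calls were lost without WT replicate 1 (camera adjusted p = 0.0642 and 0.171), and the pericyte call also without Ing1-/- replicate 1 (0.0575).

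The largest single differences in Ing1-/- belonged to probes that were near background in one genotype. Erdr1 was at least 41.7-fold higher at 1 probe and at least 7.54-fold higher at the other. A probe of Mak16, a ribosome biogenesis gene, fell by 5.34 ± 0.27 (limma adjusted p = 0.0002), with 1 of the 2 Ing1-/- arrays above background, while the other Mak16 probes changed by 0.17 and 0.26. Fut10, a fucosyltransferase, was at least 2.94-fold lower at 1 probe, another probe fell by 1.42, and the other 2 were not called. Entpd4 and Slc25a37 were at least 2.52-fold and at least 1.80-fold higher at 1 probe each, and the other probe of each changed by 0.23. Xlr4a was at least 4.10-fold lower. The glutamate transporter Slc1a3 fell by 1.22 ± 0.12, the antiviral gene Shfl by 1.22 ± 0.16 and the neuronal growth cone gene Gap43 by 1.18 ± 0.15, while Nek3 rose by 1.60 ± 0.16. In total 30 probes rose and 32 fell (limma, adjusted p under 0.05). The total of 62 was smaller without any 1 of the 8 arrays: 12 or 19 without WT replicate 1 or 2, 24 without either Gadd45a-/- array, 7 or 9 without Ing1-/- replicate 1 or 2, and 19 or 21 without DKO replicate 1 or 2. Entpd4, Erdr1, Fut10, Mak16 and Slc25a37 stayed past the threshold whichever array was left out. The other genes named for this comparison did not, save the second Dcn probe, for which this was not examined. Fut10 and Mak16 lie within 25 Mb of Ing1, and a strain variant near that gene is taken up below. For Entpd4, Erdr1 and Slc25a37 a difference between lines, rather than the loss of Ing1, was not tested.

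**Figure D2:**
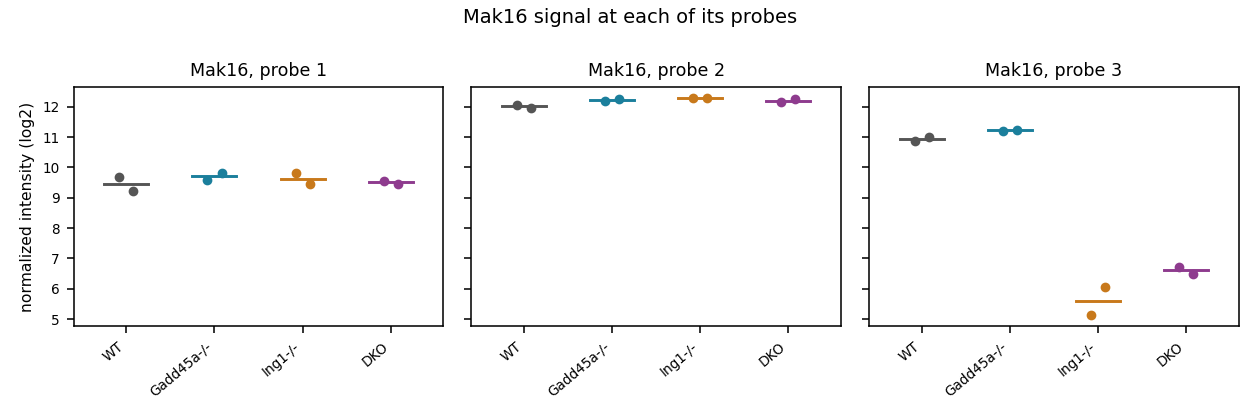
Normalized log2 intensity of the 3 Mak16 probes on each array (points, 2 per genotype) with the genotype mean (line); the vertical axis is in log2 units. At the third probe the Ing1-/- and DKO means differ from WT by -5.34 and -4.33, and at the other 2 probes by 0.05 to 0.26.

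The comparison of DKO with WT asks what changed with the loss of both genes. Interferon response genes fell, 8 of 21 measured, and none rose (median -0.66, camera adjusted p = 9.6e-11, adjusted p = 0.119 with an estimated correlation). Over the list alone 14 were lower. Isg15, a ubiquitin-like modifier induced by interferon, fell by 1.42 ± 0.19 (limma adjusted p = 0.008), Irf9, which pairs with STAT proteins, by 1.00 ± 0.13, and the immunoproteasome subunit Psmb8 by 1.13 ± 0.23. Genes of the integrated stress response fell as well, 5 of 28 (median -0.36, camera adjusted p = 1.11e-10, adjusted p = 0.119 with an estimated correlation). The hormone gene Fgf21 was at least 2.71-fold lower, Trib3 fell by 1.30 ± 0.17, the amino acid transporter Slc7a3 by 1.08 ± 0.14 and the transaminase Gpt2 by 0.85 ± 0.14. Cholesterol synthesis genes were lower with no single call over all probes and 7 over the list alone (16 measured, median -0.39, camera adjusted p = 7e-05, adjusted p = 0.171 with an estimated correlation), although a dimmer probe of Insig1 fell by 0.81.

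In the matrix list 7 of 40 genes fell and 1 rose in DKO (median -0.22, camera adjusted p = 0.000101, adjusted p = 0.239 with an estimated correlation). Lum was at least 2.59-fold lower, Dcn fell by 1.74 ± 0.12, the microfibril-associated gene Mfap4 by 1.92 ± 0.17 and Col15a1 by 0.89 ± 0.19. Contractile genes and TGF-beta targets were higher (28 measured, 2 rising and 1 falling, median 0.23, camera adjusted p = 9.45e-05, adjusted p = 0.119 with an estimated correlation): smooth muscle myosin Myh11 rose by 1.03 ± 0.16 and Tgfb2 by 0.85 ± 0.16, while Tgfbi fell by 0.72 ± 0.16. Secretory genes went both ways, 6 lower and 1 higher of 25, and the list did not pass (median 0.01, while its test pointed to lower values, camera adjusted p = 0.182). Mmp13 was at least 3.20-fold lower, Igfbp3 at least 3.09-fold lower, Cxcl1 fell by 1.38 ± 0.14 and Mmp9 by 1.23 ± 0.14.

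Markers of other cell types moved in DKO as follows. Cartilage and bone markers were higher, 3 of 7 (median 0.77, camera adjusted p = 0.00131, adjusted p = 0.119 with an estimated correlation), with Col2a1 higher by 2.99 ± 0.13, Bmp4 by 1.73 ± 0.15 and the osteoblast transcription factor Sp7 at least 2.44-fold. Epithelial markers were higher, 3 of 6 (median 0.93, camera adjusted p = 0.00462, adjusted p = 0.141 with an estimated correlation), with Pkp1 higher by 1.79 ± 0.15 and Krt19 at least 2.10-fold; for Pkp1, 1 of the 2 WT arrays was above background. Skeletal muscle markers passed as higher with no member past the threshold over all probes (8 measured, median 0.37, camera adjusted p = 0.00153, adjusted p = 0.119 with an estimated correlation). With no detection filter the cartilage and muscle lists were not called (camera adjusted p = 0.501 and 0.0666). Neural markers passed as lower (8 measured, median -0.40, camera adjusted p = 0.037, adjusted p = 0.239 with an estimated correlation) and pericyte markers as higher (7 measured, median 0.27, camera adjusted p = 0.0468, adjusted p = 0.266 with an estimated correlation). Both were lost without WT replicate 1 (camera adjusted p = 0.0849 and 0.139) or DKO replicate 1 (0.0823 for both). The neural call was also lost without Gadd45a-/- replicate 1 or 2 (camera adjusted p = 0.0565 and 0.0568), with normexp at offset 50 (0.0645), no detection filter (0.241) and all probes of each gene (0.0839), and the pericyte call without Gadd45a-/- replicate 2 (0.0502) or DKO replicate 2 (0.0583) and with the authors' processed values (0.0525). Macrophage and blood markers did not differ detectably from WT (median 0.09, camera adjusted p = 0.984, none called).

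Outside these lists Smoc1 rose by 2.46 ± 0.12, the peptide hormone gene Cck by 2.14 ± 0.11, the kinase gene Dmpk by 2.10 ± 0.13 and the sulfotransferase gene Chst7 by 1.91 ± 0.14. Slco4a1, an organic anion transporter, was at least 2.26-fold higher. Tenm4 was at least 2.96-fold lower, Enox1 at least 2.30-fold lower, and Itgbl1 fell by 2.03 ± 0.22. The probes of Mak16, Fut10, Entpd4 and Slc25a37 called in Ing1-/- were called in DKO too: Mak16 fell by 4.33 ± 0.27, Fut10 was at least 2.85-fold lower, and Entpd4 and Slc25a37 were at least 2.09-fold and at least 1.80-fold higher. In all, 275 probes rose and 290 fell in DKO (limma, adjusted p under 0.05), for 221 and 215 named genes. The total of 565 became 253 without WT replicate 1, 140 without DKO replicate 1 and 158 without DKO replicate 2. Isg15, Irf9, Psmb8, Fgf21, Trib3, Slc7a3, Gpt2, Col15a1, Myh11, Tgfb2, Tgfbi, Igfbp3, Sp7 and Krt19 each lost the call in DKO with at least 1 choice of the array left out. The other genes given as called in DKO in these 4 paragraphs kept it in every such fit, save Insig1, which was not examined in this way.

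**Figure D3:**
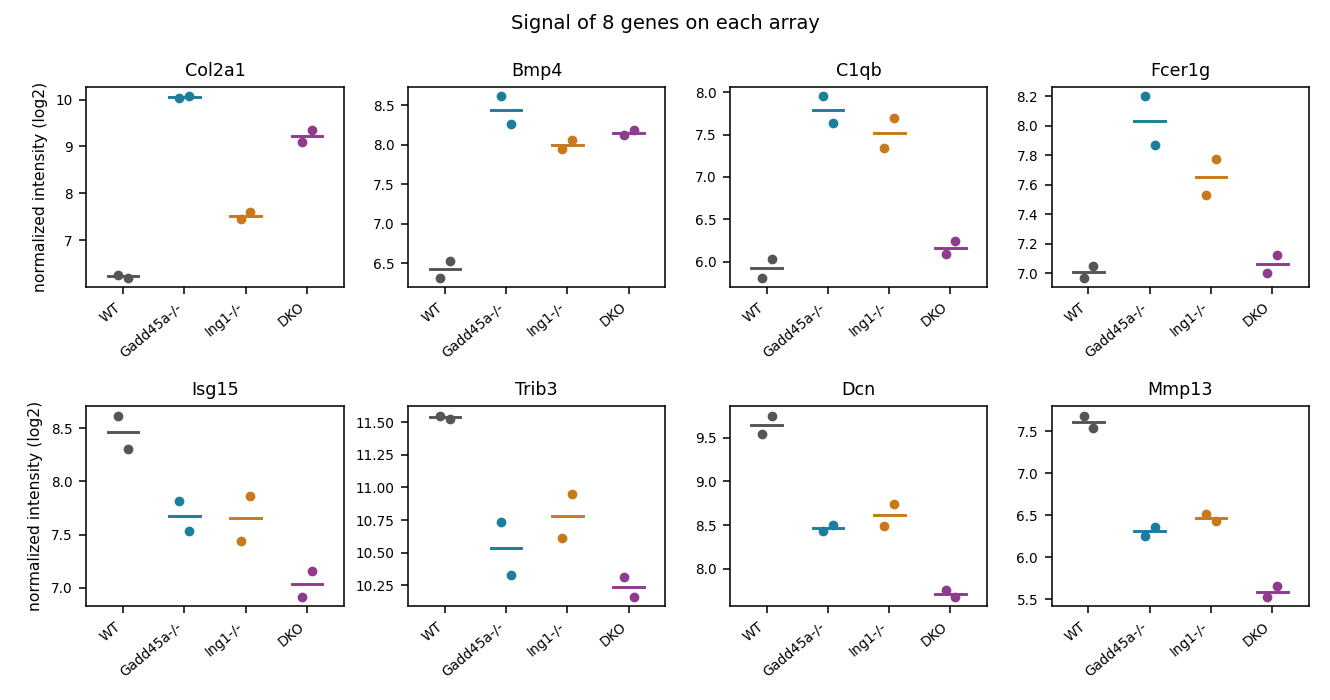
Normalized log2 intensity of 8 genes on each array (points, 2 per genotype) with the genotype mean (line); each panel has its own vertical axis, in log2 units. Col2a1 and Bmp4 are higher than WT in the 3 knockout genotypes, C1qb is higher in the single knockouts and near WT in DKO, and Isg15, Trib3, Dcn and Mmp13 have their lowest means in DKO.

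DKO was compared with each single knockout, which asks what the loss of the second gene adds and uses no WT array in the difference. Against Gadd45a-/-, macrophage and blood markers were lower, 4 of 10 (median -0.99, camera adjusted p = 4.37e-15, adjusted p = 0.0728 with an estimated correlation), with C1qb lower by 1.63 ± 0.17, Lyz2 by 1.20 ± 0.10 and Lyz1 by 1.00 ± 0.13. The neural markers Gap43 and Ngfr fell by 1.36 ± 0.15 and 0.94 ± 0.14, Ngfr with 1 of the 2 DKO arrays above background (list of 8 measured, median -0.53, camera adjusted p = 0.000226, adjusted p = 0.156 with an estimated correlation), and Mfap5 rose by 1.14 ± 0.11. Tmem267, Mmp3 and the homeobox gene Isl1 were among the largest rises, at least 2.44-fold, at least 2.35-fold and by 1.59 ± 0.16, Isl1 with 1 Gadd45a-/- array above background. With no single call over all probes, interferon genes passed as lower (21 measured, median -0.22, camera adjusted p = 0.00102, adjusted p = 0.279 with an estimated correlation), and skeletal muscle markers (8 measured, median 0.38, camera adjusted p = 2.42e-05, adjusted p = 0.109 with an estimated correlation) and contractile genes (28 measured, median 0.12, camera adjusted p = 0.0104, adjusted p = 0.225 with an estimated correlation) as higher. Each of the 9 genes named here lost its call without at least 1 Gadd45a-/- array and without at least 1 DKO array. Kept whichever array was left out were the calls of Mak16, which fell by 4.61 ± 0.27 at 1 probe, and of Entpd4 and Slc25a37, at least 2.15-fold and at least 1.85-fold higher at 1 probe each. In total 23 probes rose and 35 fell (limma, adjusted p under 0.05). That total of 58 was 5 without either Gadd45a-/- array, 23 without either Ing1-/- array, and 5 or 4 without DKO replicate 1 or 2.

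Against Ing1-/-, macrophage and blood markers were again lower in DKO, 3 of 10 (median -0.58, camera adjusted p = 6.97e-09, adjusted p = 0.163 with an estimated correlation). Oxidative stress genes were higher, 2 of 21 (median 0.22, camera adjusted p = 7.67e-05, adjusted p = 0.197 with an estimated correlation): the glutathione transferase Gsta4 rose by 1.63 ± 0.14 and the quinone reductase Nqo1 by 0.98 ± 0.17. Cartilage and bone markers were higher, 2 of 7 (median 0.44, camera adjusted p = 0.000907, adjusted p = 0.163 with an estimated correlation), with Sp7 at least 2.51-fold higher. Cholesterol synthesis genes were lower with no single call over all probes (16 measured, median -0.34, camera adjusted p = 7.67e-05, adjusted p = 0.197 with an estimated correlation). Pparg, the adipogenic nuclear receptor, rose by 1.17 ± 0.16 and Cck by 2.17 ± 0.11, while the neuropeptide gene Npy was at least 1.61-fold lower and Erdr1 at least 41.5-fold lower at 1 probe. Of these genes Cck and Erdr1 kept their calls whichever array was left out. Gsta4, Nqo1, Pparg and Npy each lost it without any 1 of the Ing1-/- and DKO arrays, and Sp7 without either Ing1-/- array or DKO replicate 2. Camera called 8 more lists, with adjusted p from 0.163 to 0.442 with an estimated correlation. Matrix genes as lower and epithelial and skeletal muscle genes as higher kept camera's call whichever array was left out, the epithelial list losing it with no detection filter (camera adjusted p = 0.056). The other 5 did not. Without Ing1-/- replicate 2 all 5 lost the call: interferon (camera adjusted p = 0.467), Hox (0.124), integrated stress response (0.207) and endothelial genes (0.408), called as lower, and heat shock genes (0.258), called as higher. Without DKO replicate 2 the Hox, integrated stress response and heat shock calls were lost (0.12, 0.0612 and 0.12), without Ing1-/- replicate 1 the Hox call (0.0999) and without DKO replicate 1 the endothelial call (0.183). Heat shock and endothelial genes also lost it without Gadd45a-/- replicate 1 or 2 (0.0519 and 0.0516 for both lists), and endothelial genes without WT replicate 1 or 2 (0.0633 and 0.0661). With no detection filter interferon, Hox and endothelial genes were not called (0.132, 0.382 and 0.684), with all probes of each gene Hox and endothelial genes were not (0.0669 and 0.0764), and with normexp at offset 50 Hox genes were not (0.0552). In total 100 probes rose and 65 fell (limma, adjusted p under 0.05). That total of 165 was 22 or 5 without Ing1-/- replicate 1 or 2 and 8 without either DKO array.

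Departure of DKO from the sum of the single-knockout changes was tested as an interaction on the log2 scale. The complement gene C1qb had an interaction of -3.23 ± 0.24 (limma adjusted p = 0.0091), C1qc of -2.72 ± 0.33 and Laptm5, a lysosomal membrane protein of blood cells, of -1.58 ± 0.16, and in the macrophage and blood list 5 of 10 were below it and none above (median -1.49, camera adjusted p = 1.76e-19). This was the only list call in any comparison to hold with the correlation estimated (adjusted p = 0.0448 with an estimated correlation). Col2a1 and Bmp4, high in each knockout, had interactions of -2.11 ± 0.18 and -1.87 ± 0.21. Against WT, Bmp4 was higher by 2.02, 1.58 and 1.73 in Gadd45a-/-, Ing1-/- and DKO, and Col2a1 by 3.81, 1.29 and 2.99. A deviation of the WT arrays alone would also give the Bmp4 interaction and could add to that of Col2a1. C1qb was above background on 1 WT array, and C1qc on 1 WT and 1 DKO array. Camera called 8 further lists, with adjusted p from 0.254 to 0.406 with an estimated correlation. Among them, the integrated stress response had medians against WT of -0.33 in Gadd45a-/-, -0.32 in Ing1-/- and -0.36 in DKO. A deviation of the WT arrays alone would also give its interaction. Secretory, integrated stress response, oxidative stress and skeletal muscle genes as above the sum kept camera's call whichever array was left out. Hox, endothelial and cartilage genes, called as below it, and interferon genes, called as above it, did not. Hox genes lost the call without WT replicate 1 (camera adjusted p = 0.0789) and with no detection filter (0.194). Endothelial genes lost it without WT replicate 1 (0.106), Gadd45a-/- replicate 1 (0.0818), Ing1-/- replicate 2 (0.328) or DKO replicate 1 (0.145), with no detection filter (0.734) and with all probes of each gene (0.0858). Cartilage genes lost it without WT replicate 2 (0.0567), Gadd45a-/- replicate 1 (0.0507), Ing1-/- replicate 2 (0.14) or DKO replicate 1 (0.115), and with no detection filter their test turned direction (0.979). Interferon genes lost it without WT replicate 1 (0.201), Gadd45a-/- replicate 1 or 2 (0.0507 and 0.134), Ing1-/- replicate 1 (0.527) or DKO replicate 1 or 2 (0.0655 and 0.0945), with the authors' processed values (0.0598), with no detection filter (0.326) and with all probes of each gene (0.113). Altogether 2 probes lay above the sum and 20 below (limma, adjusted p under 0.05). That total of 22 was 7 without WT replicate 2, 1 or 2 without Gadd45a-/- replicate 1 or 2, 2 or 4 without Ing1-/- replicate 1 or 2 and 1 or 4 without DKO replicate 1 or 2. The share above the sum, 9.09%, was 33.3% without WT replicate 1, 14.3% without WT replicate 2 and 0% without any other array. Only Erdr1 stayed past the threshold whichever array was left out.

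Calls shared between the comparisons with WT were counted by direction. Between Gadd45a-/- and Ing1-/-, 18 probes were higher in both and 8 lower in both, where independent lists would share 0.278 and 0.129, and 1 probe was called in opposite directions. Gadd45a-/- and DKO shared 101 higher and 41 lower (2.55 and 1.17 for independent lists), and Ing1-/- and DKO shared 21 and 25 (0.555 and 0.624 for independent lists). Simulated unchanged groups against shared controls shared 0, 0 and at most 1 call over 100 draws, but such groups give almost no calls to share, so this does not show how many shared calls the controls add. Probes called the same way against WT in all 3 knockout genotypes numbered 21, of which 14 were higher, Col2a1, Bmp4, Smoc1 and Pde4dip among them, and 7 lower, Lum, Dcn, Mmp13 and Cxcl1 among them. The covariance of log2 fold changes across probes was 0.0433 between the single knockouts against 0.0156 simulated. It was 0.0602 against 0.0156 for Gadd45a-/- and DKO, and 0.0531 against 0.0155 for Ing1-/- and DKO. Covariance also grows with the size of the changes. In the same order the correlation was 0.56, 0.63 and 0.58, against 0.5 simulated for each. Signs matched for 71%, 69.3% and 68.8% of probes, against 66.7%, 66.6% and 66.6% simulated. By these 2 measures the excess was small. The controls were not split, since that leaves 1 WT array to each comparison, and part of the excess may come from the shared controls. Calls shared with DKO, and those in all 3 knockout genotypes, were not recounted with an array left out. They cannot exceed each comparison's own total in such fits, which fell as given above. The 26 calls shared by the single knockouts fell to between 1 and 8 when any 1 array was left out, with 3 or 8 without WT replicate 1 or 2, 7 or 8 without Gadd45a-/- replicate 1 or 2, 1 or 3 without Ing1-/- replicate 1 or 2 and 7 without either DKO array.

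Lists tied to the functions of the 2 targeted genes were tested in the same way. In the 3 comparisons with WT, camera called neither the Sin3/HDAC complex, nor base and nucleotide excision repair, nor the Gadd45 and ING family, nor DNA methylation and demethylation, nor imprinted genes. Dnmt3l, a cofactor of the de novo DNA methyltransferases, was the single member of the methylation list to pass. It was at least 1.94-fold lower in DKO, a call lost without DKO replicate 2 (limma adjusted p = 0.0552). Its calls as lower in Gadd45a-/- and Ing1-/- were lost whichever of the 8 arrays was left out, and its other probe was not called. Fry, a rotation test that does not weigh a list against the other genes, called the methylation list lower in Ing1-/- (fry adjusted p = 0.041) and DKO (0.0113). Camera called the p53 target list higher in Ing1-/- (29 measured, median 0.18, none called, camera adjusted p = 0.02, adjusted p = 0.157 with an estimated correlation), a call lost without WT replicate 1 or 2 (camera adjusted p = 0.0519 and 0.0602) and without Ing1-/- replicate 2 (camera adjusted p = 0.0635). Camera did not call it in Gadd45a-/- (median 0.06, camera adjusted p = 0.55) or DKO (median 0.14, camera adjusted p = 0.123), while fry called it higher in all 3 (fry adjusted p = 0.0403, 0.00325 and 0.00592 in Gadd45a-/-, Ing1-/- and DKO). Ribosomal protein and hypoxia and glycolysis lists were not called by camera in any comparison with WT, and fry called the hypoxia list lower in Gadd45a-/- (fry adjusted p = 0.0279).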

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

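The label test, the 25 Mb windows and the count of other cell types below were chosen after the results were seen, and the idea of mixed-in macrophages came from the first macrophage list. A test of the interaction found 9 named probes whose change in DKO differed from the sum of the single-knockout changes. The interaction was -6.68 for Erdr1, -3.61 for Fcrls, -3.23 for C1qb, -2.72 for C1qc, -2.11 for Col2a1, -1.87 for Bmp4, -1.62 for Fcer1g, -1.58 for Laptm5 and 3.49 for Xlr4a. Each value also rests on the WT arrays, and a deviation of those arrays alone would give that of Bmp4 too. The Erdr1 and Fcrls probes were not well above background in WT or DKO, nor the Xlr4a probe in Ing1-/-, so the sizes of these 3 interactions depend on the background correction. Other sizes moved with the processing too. Over the alternatives C1qb ranged from -3.657 to -1.687, C1qc from -3.244 to -1.287, Fcer1g from -1.786 to -1.012 and Bmp4 from -2.046 to -1.134. With each array left out in turn, only the Erdr1 interaction stayed past the threshold every time.

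Macrophage markers were higher in both single knockouts and near WT in DKO. Of the 7 other cell type lists 3 had a median above 0.3 in Gadd45a-/- and 1 in Ing1-/-. In Gadd45a-/- these were cartilage (1.28), epithelial (0.77) and mesothelial markers (0.39), while the endothelial median was -0.013. So not every other list rose. The medians were known when the count and its limit were chosen, so it is no independent test of a general gain of other cell types. Macrophages mixed into the single-knockout cultures are a candidate explanation: a second macrophage list, of which 14 of 67 genes were measured, had a median log2 change of 0.052 in Gadd45a-/- (percentile 69.5 of matched random lists) and 0.147 in Ing1-/- (percentile 98), so the rise set beforehand was reached in Ing1-/- only. In DKO its median was -0.009 against WT (percentile 37.22), -0.121 against Gadd45a-/- (percentile 3.56) and -0.133 against Ing1-/- (percentile 3.68). Its interaction was -0.21 (percentile 1.58). Mixing would give these signs, but so would other causes of the pattern, and the DKO values were not part of the prediction set beforehand. Of the 14 genes 8 were higher in sign in Gadd45a-/- and 10 in Ing1-/-. Among dim members Cx3cr1 changed by 1.05 and 0.91, Ms4a6d by 0.82 and 0.84, and Ms4a7 by 0.70 and 0.79. Alox5ap changed by 0.75 and 0.48 and Tbxas1 by 0.63 and 0.62. Of these rises only that of Cx3cr1 in Gadd45a-/- was called. Bcl2a1b, also dim, changed by -0.18 and -0.41, and Apobr by -0.69 and -0.51. The brightest members, Arhgdib, Stab1 and Cyba, changed by -0.10 to 0.17. The high baseline of those 3 would hide a small admixture, so mixing cannot be told apart from other explanations. A change within fibroblasts through the targeted genes, and a difference between lines, were not tested.

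Gadd45a probes were brighter on the arrays labelled Gadd45a-/- and DKO than on WT. A swap of knockout and control labels would need arrays that lack the signal, and both probes were above background on 8 of 8 arrays. If the probes lie inside the deleted part, this signal goes against the knockout labels themselves. If they lie outside it, the signal does not bear on a swap. The sources used here do not give the deleted part. A transcript left by the targeted allele was not tested, so the labels and such a transcript cannot be told apart here. Both probes did split the genotypes by their Gadd45a label. Mean log2 intensities were 11.82 and 11.74 in Gadd45a-/- and DKO against 10.82 and 10.13 in WT and Ing1-/- at the first probe. At the second they were 10.91 and 10.93 against 9.62 and 9.17. The grouping thus goes with the labels, but an exchange of both groups as a whole would keep the same split.

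Large changes in Ing1-/- and DKO included genes on the chromosome of Ing1 (Mak16, Fut10, Nek3 and, named after its values were seen, Smim19), and a strain variant carried with the targeted Ing1 allele could alter how a probe binds. Within 10 Mb of Ing1, 0 of 41 genes were called in Ing1-/- (odds ratio 0, 95% interval 0 to 15.1, Fisher's exact test, two-sided) and 1 in DKO (odds ratio 0.471, interval 0.0116 to 2.79); near Gadd45a, with 0 of 37 called, the odds ratio was 0 in Gadd45a-/- (interval to 5.74) and 0 in DKO (interval to 1.98). All 4 values met the bound set beforehand for excluding a strain variant, but these intervals include odds ratios above 1; the first reading, that they exclude it, was changed after the values were seen to one that leaves it open. In a 25 Mb window, drawn once the called genes near Ing1 were known, the odds ratio was 7.01 in Ing1-/- (Fisher's exact p = 0.0035) and 2.39 in DKO (Fisher's exact p = 0.017), which is no independent evidence. The same window around Gadd45a gave 2.02 in Gadd45a-/- and 1.99 in DKO (Fisher's exact p = 0.13 and 0.019). Around the gene that was not targeted it gave 0.549 near Ing1 in Gadd45a-/- (interval 0.0137 to 3.18) and 0.917 near Gadd45a in Ing1-/- (interval 0.0227 to 5.4), each with 1 gene called (Fisher's exact p = 1). Within 25 Mb of Gadd45a the genes called in Gadd45a-/- and in DKO included Hoxa5, Hoxa7 and Nt5c3. The median log2 change there was -0.025 in Gadd45a-/- (percentile 1.6 of matched random lists) and -0.034 in DKO (percentile 0.87). In Ing1-/-, where Gadd45a was not targeted, it was -0.009 (percentile 5.87). A strain variant stays open. Windows around other called genes, such as Entpd4, Slc25a37 and Erdr1, were not examined.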

How the results depend on the processing

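The count without the neighbourhood of Ing1 and the sex chromosomes was chosen after the data were seen. Of 175 named values, none changed direction under any alternative: of 1740 values under other settings 211 lost their call, and of 1400 with 1 array left out 546 did. Apart from Gadd45a, these values were named because they were called, the largest changes only where groups did not overlap. A change of direction was therefore unlikely from the start, and its absence adds little. The 3 gained calls were all of Gadd45a in Ing1-/-. They came with normexp at offset 50 (limma adjusted p = 0.024), no background correction (0.0114) and an intensity trend (0.00361), against 0.074 as reported. Sizes moved as well. Over the alternatives the log2 fold change in Gadd45a-/- against WT ranged from 2.683 to 4.008 for Col2a1, 1.243 to 2.197 for Bmp4 and 0.98 to 2.126 for C1qb. The cause of these moves and of those below was not tested. In the order Gadd45a-/-, Ing1-/- and DKO against WT, DKO against Gadd45a-/-, DKO against Ing1-/-, interaction and calls shared by the single knockouts, the reported counts were 198, 62, 565, 58, 165, 22 and 26.

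In that order the counts were 87, 20, 317, 17, 56, 6 and 8 with no detection filter, 108, 20, 369, 17, 66, 6 and 8 with detection p under 0.05 in 2 arrays, and 43, 14, 200, 9, 27, 2 and 4 at an adjusted p under 0.01. With a trend and robust variances they were 335, 140, 842, 110, 280, 40 and 70, and with no background correction 292, 123, 766, 92, 260, 37 and 62. The share of higher calls with no background correction was 56.5% in Gadd45a-/- and 36.6% in Ing1-/-, against 69.7% and 48.4%. It went the other way in fits to only the groups compared (84.8% and 57.1%) and at an adjusted p under 0.01 (79.1% and 57.1%). In the interaction the share above the sum was 9.09%, and it was 24.3% with no background correction, 25% with a trend and robust variances, 18.8% with normexp at offset 50, 15% with the authors' processed values, 16.7% with either looser filter, 5.88% without genes near Ing1 and on sex chromosomes and 0% at an adjusted p under 0.01. Array weights gave 130, 39, 583, 98, 275, 22 and 14, and requiring a 2-fold change 103, 38, 229, 37, 89, 22 and 12. Fits to only the groups compared gave 33, 7, 265, 23 and 120. With normexp at offset 50, Ing1-/- had 116 calls and 56 were shared, and with median scaling DKO against Gadd45a-/- had 35. Without genes near Ing1 and on sex chromosomes the counts were 188, 50, 538, 50, 157, 17 and 24.

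With 1 array left out, the lone array of its genotype being assumed to vary as the others, counts ranged from 37 to 140, 7 to 24, 140 to 498, 4 to 77, 5 to 186, 1 to 21 and 1 to 8. The share of higher calls became 85% in Gadd45a-/- without its replicate 2, 60% against 39.7% in DKO against Gadd45a-/- without DKO replicate 1, and 75% to 87.5% against 60.6% in DKO against Ing1-/- without Ing1-/- replicate 2 or either DKO array. In the comparisons of DKO with a single knockout these shares rest on very few calls, so they do not show a shift in direction. Lists called by camera ranged from 8 to 11, 5 to 10, 8 to 11, 5 to 9, 7 to 12 and 6 to 10 in the same order of comparisons, against 10, 9, 10, 5, 12 and 9 as reported; the values 5 without WT replicate 1, 9 without Gadd45a-/- replicate 2 and 7 without Ing1-/- replicate 2 moved by over 1.5 times. With an estimated correlation 0, 0, 0, 0, 0 and 1 lists were called. Fry called 10, 9 and 14 lists in Gadd45a-/-, Ing1-/- and DKO against WT, not all of them the lists camera called. It called 3, 6 and 4 lists in DKO against Gadd45a-/-, DKO against Ing1-/- and the interaction. Camera with all probes of each gene gave 12 in DKO against Gadd45a-/-, and with no detection filter 5 in the interaction.

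With replicate number as a block the interaction had 10 calls and the single knockouts shared 17; the other counts stayed within 1.5 times, and camera no longer called the cell cycle list in Gadd45a-/- (adjusted p = 0.054) or the interferon list in the interaction (0.053). The numbers were not taken as pairing, since the labels do not state one. Deviations of same-numbered arrays correlated between -0.09 and 0.28 across genotypes, and 6 of 8 arrays correlated best with their own number. With 2 arrays per genotype both give the same answer by construction, so these values neither show nor exclude a pairing. Signal over background limits the values of dim probes. Between 2 genotypes, named probes not well above background on any array of 1 of them are given as bounds. Those above it on 1 of 2 arrays are given as differences, whose sizes it limits too.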

Other observations

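The Hox genes split by member. Hoxa5 and Hoxa7 rose in Gadd45a-/- (by 0.84 ± 0.14 and 0.84 ± 0.15) and in DKO (by 0.93 ± 0.14 and 0.76 ± 0.15), and Hoxd8 fell by 1.04 ± 0.11 in DKO, while the Hox list was not called against WT. Hoxa5 and Hoxa7 lie within 25 Mb of Gadd45a, so a strain variant carried with its targeted allele cannot be told apart from its loss. The Hoxd8 call was kept whichever array was left out. In Gadd45a-/- the Hoxa7 call was lost without any 1 of the 8 arrays and the Hoxa5 call without any 1 WT, Gadd45a-/- or DKO array. In DKO the Hoxa7 call was lost without any 1 WT, Ing1-/- or DKO array, and the Hoxa5 call without WT replicate 1 or either DKO array. Among neural markers in DKO, Gap43 fell by 1.37 ± 0.15 and Ngfr fell by 0.95 ± 0.14, the latter with 1 of the 2 DKO arrays above background, while nestin (Nes) rose by 0.87 ± 0.15. Of the endothelial markers Emcn was at least 2.43-fold higher in DKO and Flt1 fell by 0.85 ± 0.13. Gap43 and Emcn kept their calls whichever array was left out, Nes and Flt1 lost theirs without WT replicate 1 or either DKO array, and Ngfr without WT replicate 1 or DKO replicate 1.

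Different probes of 1 gene gave different answers for several of the largest changes. In Ing1-/- the other probe of Entpd4 and that of Slc25a37 changed by 0.23, where the called probes were at least 2.52-fold and at least 1.80-fold higher. In DKO the called Pde4dip probe rose by 2.40, and of its other 3 probes 2 changed by -0.10 and 0.05 and 1 was not above background in WT or DKO. At 1 Erdr1 probe Ing1-/- was at least 41.7-fold higher than WT and DKO was not well above background, while at the other Ing1-/- was at least 7.54-fold and DKO at least 4.72-fold higher. By contrast all 3 Col2a1 probes passed in DKO.

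A gain or loss of a whole chromosome in a cell line was tested as a hypothesis, with its limit set before the values were computed. The largest median log2 change of any autosome in the 3 comparisons with WT was 0.038 in size, under the limit of 0.3, which argues against it.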
